A study of Drosophila melanogaster with 6 samples.

How the data were processed

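The series holds 6 single-channel arrays of wing imaginal discs of Drosophila melanogaster, 3 from discs that expressed Yki under the apterous driver and 3 from discs that expressed Yki with RNA interference against pan, grouped by the sample titles. Per the labels, discs were dissected 7 days after transgene induction, total RNA was isolated with TRIzol and labelled with biotin. The values used are log2 expression levels that the authors deposited in 2 tables, a matrix of the whole series and the series matrix. Both tables hold the same 11325 features, and their values differ by at most 5.0e-09, so the matrix of the whole series was used and the planned analysis of the other table gives identical results. The array type's background correction, normalization and summarisation are not given in the sources used here. The deposited log2 values run from 2.74 to 14.06, the array means from 8.516 to 8.524, and the medians from 8.410 to 8.515. Each feature reaches at least 5.91 in 3 or more arrays, so features below a minimum were probably removed before deposit, and genes that are silent in both groups are not covered. Per the labels, the submitters analysed 6 samples at gene level with limma and selected genes by an adjusted p under 0.05 and a log2 fold change of at least 1, and the same test and thresholds were used here. Nothing in the labels states that the samples came from separate crosses or animals, so p-values measure the spread between these samples, which may be technical.

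Features were named from the platform annotation supplied with the series matrix. Of the 11325 features, 10156 had 1 gene symbol, 313 several and 856 none there, and a feature listed with no symbol is unnamed here, not without a gene. Another 17 features with 1 symbol but several FlyBase numbers were not named. Symbols of 9975 of the 10139 named features were updated through their Entrez numbers in a RefSeq gene table of the assembly Release 6 plus ISO1 MT, which served for names and gene spans only, since the build behind the arrays is not given in the sources used here. The 22 genes with more than 1 feature were represented by the feature with the highest mean over the 6 arrays, which left 11303 tested features, 10117 named genes and 1186 unnamed features. Unnamed features were tested and counted but are not described. The pan gene and some other genes of the planned lists, among them wg, Diap1, Myc, ban and fz3, are not reported here, so the planned check of the knockdown was not run.

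The groups were compared with limma (lmFit and eBayes with default settings, no covariate, Yki + pan RNAi minus Yki), and p-values were adjusted by the Benjamini-Hochberg method over the 11303 features. A feature was called at an adjusted p under 0.05 with an absolute log2 fold change of at least 1. A gene list member is said to have risen or fallen at an adjusted p under 0.05 whatever its fold, and the counts adjusted over the list alone use the members' p-values only. Before the data were examined, 36 gene lists were fixed, 28 of pathways and processes and 8 of other cell types or sample composition. After the files were read, current symbols were added as aliases for 5 listed genes (Delta, MsrA, mTor, dysf and dachs). Lists with at least 3 measured members were tested for a shift against all other features with camera at its preset inter-gene correlation of 0.01, adjusted over the 35 lists tested. The list of salivary gland markers had 2 measured members and was not tested. Camera with a correlation estimated from the arrays gave adjusted p-values of 0.302 to 0.57 for the 15 lists called. Thus 0 calls hold with it, and 5 of the 35 lists had an unadjusted p under 0.05. This setting also bases the test on the few residual degrees of freedom of the 6 arrays. The loss of calls is therefore not due to correlation between genes alone. The JAK/STAT list had an estimated correlation of −0.042, below the preset 0.01. Its camera p before adjustment still rose from 0.0000441 to 0.0132. Lists share members, such as dve and Dll in the Wg-activated and pouch lists. Of the cell type markers, 1 of 12 haemocyte, 0 of 10 tracheal, 1 of 8 myoblast, 3 of 8 fat body, 0 of 9 muscle, 1 of 12 neuron and glia and 3 of 6 sex composition markers also stand in another list.

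Genes were named by a rule fixed before the data were examined. It takes 11 genes always named, of which yki, CycE, ex, nkd and Notum were measured under their names, the 8 largest rises and the 8 largest falls among called genes with non-overlapping groups, and up to 4 members per list with the lowest p among those past the adjusted p (or the 1 with the lowest p). From the list members so chosen the text mostly gives 2 to 4 per list, and members whose call ended on leaving out 1 array are mostly given as counts. Genes named in the closing part outside this rule are said there to have been chosen after their values were seen.

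The analysis code was tested on simulated normal values with the mean and residual spread of each of the 11303 features, in 5 runs with 250 changed genes of each size over all runs. Of genes changed by 0.5, 1.25, 2 and 3 on the log2 scale, 74%, 97.2%, 99.6% and 100% passed the adjusted p, and 0%, 96%, 99.6% and 100% were called. Of 55357 unchanged genes over the 5 runs, 69 passed the adjusted p. A list shifted by 0.3 was called in 5 of 5 runs, with 2 calls of other lists over all runs. Values were drawn independently for each gene, whereas correlations estimated from the arrays reached 0.485 for the proteasome and 0.65 for the heat shock list. These runs therefore give no rate of false list calls for the arrays.

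The alternatives fixed in advance were median centring, quantile normalization, leaving out dim features (those with a mean at or below the 30th percentile, 3387 features), no collapsing of features, eBayes with trend and robust settings, array weights, the replicate number as a block, leaving out each array in turn, a test against a log2 fold change of 0.5 (treat), a minimum log2 fold change of 0.6, and camera with an estimated correlation, camera on ranks and fry, which tests a list against no change and not against the other features. Removal of each array's trend with gene length or with signal level (splines on the log2 genomic span or on the mean level) was added after the data were seen. Software versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.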

Results

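Gene expression was measured on single-channel arrays hybridised with biotin-labelled total RNA from wing imaginal discs of Drosophila melanogaster larvae, the epithelial sacs that form the adult wing and dorsal thorax. In the 3 samples of the Yki group, the apterous driver, which is active in the dorsal compartment of the disc, expressed Yki, the fly counterpart of YAP and the growth-promoting effector of the Hippo pathway. In the other 3 samples the same driver expressed Yki together with RNA interference against pan, which encodes dTcf, the DNA-binding effector of Wg (Wnt) signalling. All discs were dissected 7 days after induction. The comparison asks which transcripts of Yki-expressing discs differ when dTcf is depleted. The sample titles name no discs without Yki and no control hairpin. Whether a change depends on Yki, or comes from the hairpin other than through dTcf, was therefore not tested. Values are log2 levels, n = 3 arrays per group throughout, changes are Yki + pan RNAi minus Yki with the SE of the limma fit, and the small number of arrays limits the precision. Pan itself was not analysed here, so the depletion was not checked in these arrays. The first principal component held 67.6% of the variance and separated the groups, and array correlations were 0.994 to 0.996 within groups and 0.980 to 0.986 between them.

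Discs with pan RNAi had lower levels of Wg-activated, Notch-target and wing pouch genes and of several genes induced by ecdysone. Levels of chinmo, tsh, many genes of the cell cycle and 6 of 9 measured JAK/STAT genes were higher. The shifts of gene lists among these were called at a preset correlation between genes. With a correlation estimated from the arrays, which also leaves the test fewer degrees of freedom, 0 of 15 calls held (adjusted p = 0.302 to 0.57). Of 11303 features tested, 173 changed at least 2-fold at an adjusted p under 0.05, 30 of them higher and 143 lower with pan RNAi. These included 143 named genes, 25 higher and 118 lower. All 173 had non-overlapping groups, as did 44.9% of all features, where chance gives 10%. The largest rises among named genes were those of CG8927 (2.59 ± 0.13, adjusted p = 0.000222), CG7512 (1.99 ± 0.09), CG15784 (1.79 ± 0.16) and chinmo (1.67 ± 0.11), a transcription factor of early larval and undifferentiated states. CG1909, the piRNA-binding Argonaute gene piwi and the cell adhesion gene sns followed with rises of 1.65, 1.57 and 1.53, and CG13894 rose 2.83-fold. The largest falls among named genes were those of wbl (−2.86 ± 0.31, adjusted p = 0.00158), which encodes an endoplasmic reticulum protein, of the serine protease inhibitor gene Spn43Aa (−2.83 ± 0.23), and of Blimp-1 (−2.82 ± 0.43), ImpE1 (−2.75 ± 0.40) and ImpE2 (−2.75 ± 0.42), which are induced by ecdysone. CG9416, CG1273 and uncNacbeta followed at −2.66, −2.65 and −2.62. The level of yki itself was 13.67 ± 0.06 (SD) without and 13.67 ± 0.05 with pan RNAi, a change of 0.00 ± 0.05 (adjusted p = 0.971). This lies near the highest value of any feature, 14.06, where a difference in transcript level can be compressed, so equal amounts were not shown.

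Without the fold minimum, 2887 features passed the adjusted p, 1369 higher and 1518 lower. When each array was centred on its median, 2086 were higher and 1086 lower. The count fell to 1815 without Yki replicate 2, to 1810 without Yki replicate 3 and to 1744 without Yki + pan RNAi replicate 1.

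**Figure D1:**
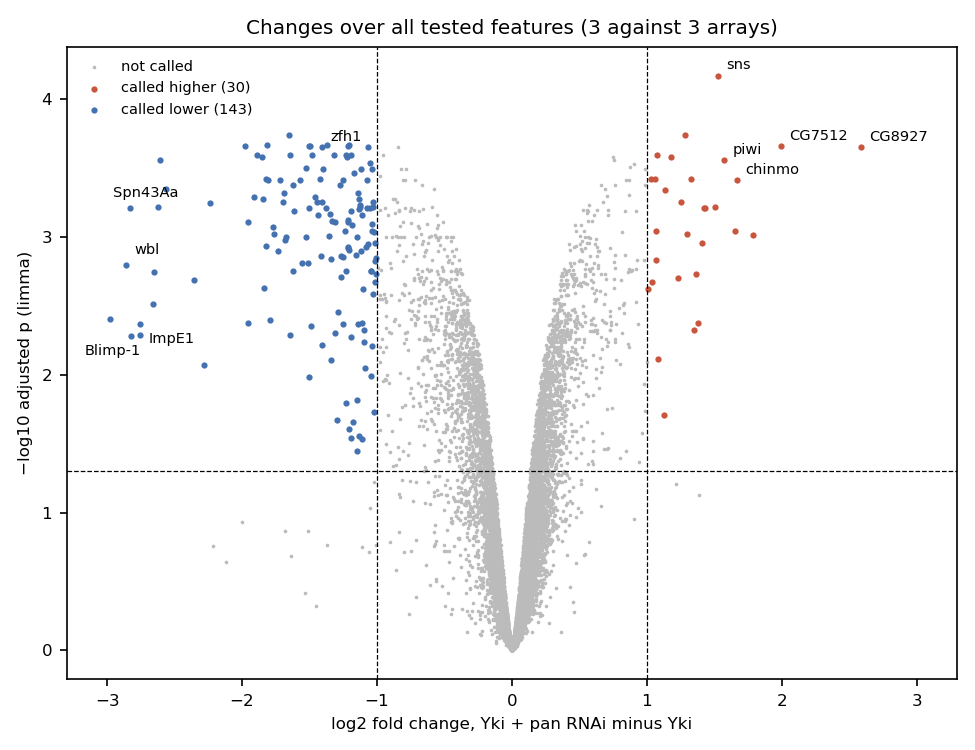
Each point is 1 of the 11303 tested features, with the log2 fold change of Yki + pan RNAi minus Yki on the horizontal axis and −log10 of the limma adjusted p on the vertical axis; dashed lines mark the thresholds. The 143 features called lower (blue) outnumber the 30 called higher (red) and include wbl at −2.86 and Blimp-1 at −2.82; the largest fall, 7.89-fold, was that of an unnamed feature.

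Genes known to be activated by Wg and dTcf in the wing disc fell as a group. Of 10 measured, 7 fell and 0 rose (7 and 1 adjusted over the list alone, 8 at an unadjusted p under 0.05), with a median change of −0.53 (camera adjusted p = 0.000281, and adjusted p = 0.346 with an estimated correlation). The proneural genes ac (−1.15 ± 0.11) and sc (−1.12 ± 0.07, adjusted p = 0.00032), which set up sensory organs, and the homeobox genes dve (−1.08 ± 0.07) and Dll (−1.02 ± 0.09) changed most. Notum, a secreted feedback inhibitor of Wg, fell by 0.67 on the log2 scale (adjusted p = 0.00785). In contrast to these, the Wg target and antagonist nkd was at 11.08 ± 0.08 (SD) without and 11.19 ± 0.05 with pan RNAi (adjusted p = 0.202). The 11 measured components of the Wg pathway went both ways, 3 up and 3 down (3 and 3 over the list alone), with a median of 0.01, a mean of −0.14 and no shift called (adjusted p = 0.686). Among them the ligand gene Wnt6 fell 2.54-fold (−1.35 ± 0.11), and shf, which encodes a secreted factor, changed by −0.29 ± 0.06. Of 3 measured genes known to be repressed by Wg, Pxn rose (0.50 ± 0.09, adjusted p = 0.00966) and Ugt36D1 fell (−0.36 ± 0.07, adjusted p = 0.0135), the latter at adjusted p = 0.0502 without Yki replicate 2. Pxn is also a marker of haemocytes, of which others rose with it. The list of Wg-repressed genes did not pass the shift test (median 0.20, adjusted p = 0.675, with 2 up and 1 down over the list alone).

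The list of the Notch pathway and its targets shifted down as well. Of 15 measured, 8 fell and 1 rose (9 and 2 adjusted over the list alone), with a median of −0.50 (camera adjusted p = 0.000281, and adjusted p = 0.346 with an estimated correlation). The Bearded-family genes E(spl)m6-BFM (−1.95 ± 0.17, 3.87-fold, adjusted p = 0.00078) and E(spl)m2-BFM (−1.27 ± 0.13), which respond directly to Notch, and ct (−0.84 ± 0.08), a gene of the wing margin, were the members with the lowest p among those that fell. Of the 8, 1 also stands in the fixed list of myoblast markers, which shifted down too. Whether the others are expressed in myoblasts was not examined. The member that rose was fng (0.34 ± 0.04, adjusted p = 0.0028), which encodes a glycosyltransferase that modifies Notch in dorsal cells.

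Genes of the wing pouch, the part of the disc that forms the blade, were lower. Of 11 measured, 6 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of −0.40 (camera adjusted p = 0.00447, and adjusted p = 0.402 with an estimated correlation). The POU-domain genes pdm2 (−1.22 ± 0.10, adjusted p = 0.000753) and nub (−1.12 ± 0.09, adjusted p = 0.000584) fell along with dve and Dll. By contrast bi, a T-box gene activated by Dpp, rose by 0.63 ± 0.05 (adjusted p = 0.00064). The pouch median was −0.26 without Yki + pan RNAi replicate 1. All 13 measured genes of hinge and notum identity changed, 5 up and 8 down (the same counts over the list alone), and the list as a whole did not pass the shift test (median −0.38, adjusted p = 0.234). The hinge genes zfh2 (0.75 ± 0.04, adjusted p = 0.000261) and tsh (1.06 ± 0.07) and the T-box gene Doc3 (0.99 ± 0.06) rose, whereas caup, an Iroquois gene of the lateral notum, fell (−0.79 ± 0.05, adjusted p = 0.00032). Among 5 dorsal compartment genes, 3 rose and 2 fell (3 and 2 over the list alone), with a median of 0.34, a mean of −0.03 and no shift called (adjusted p = 0.609). They included ap, the selector gene of dorsal cells (0.37 ± 0.04), Dr (0.49 ± 0.06) and caps (−0.73 ± 0.07, adjusted p = 0.00133).

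The Hedgehog and Dpp pathway list shifted up slightly, with 8 of 19 members higher and 1 lower (9 and 1 adjusted over the list alone) and a median of 0.10 (camera adjusted p = 0.00408, and adjusted p = 0.358 with an estimated correlation). The members that rose included inv (0.52 ± 0.05, adjusted p = 0.00106), a homeobox gene of posterior cells, and the Dpp receptor gene tkv (0.28 ± 0.04). The member that fell was kn (−1.14 ± 0.08, adjusted p = 0.000476), a Hedgehog target in the centre of the pouch. The median was 0.15 with each array centred on its median.

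**Figure D2:**
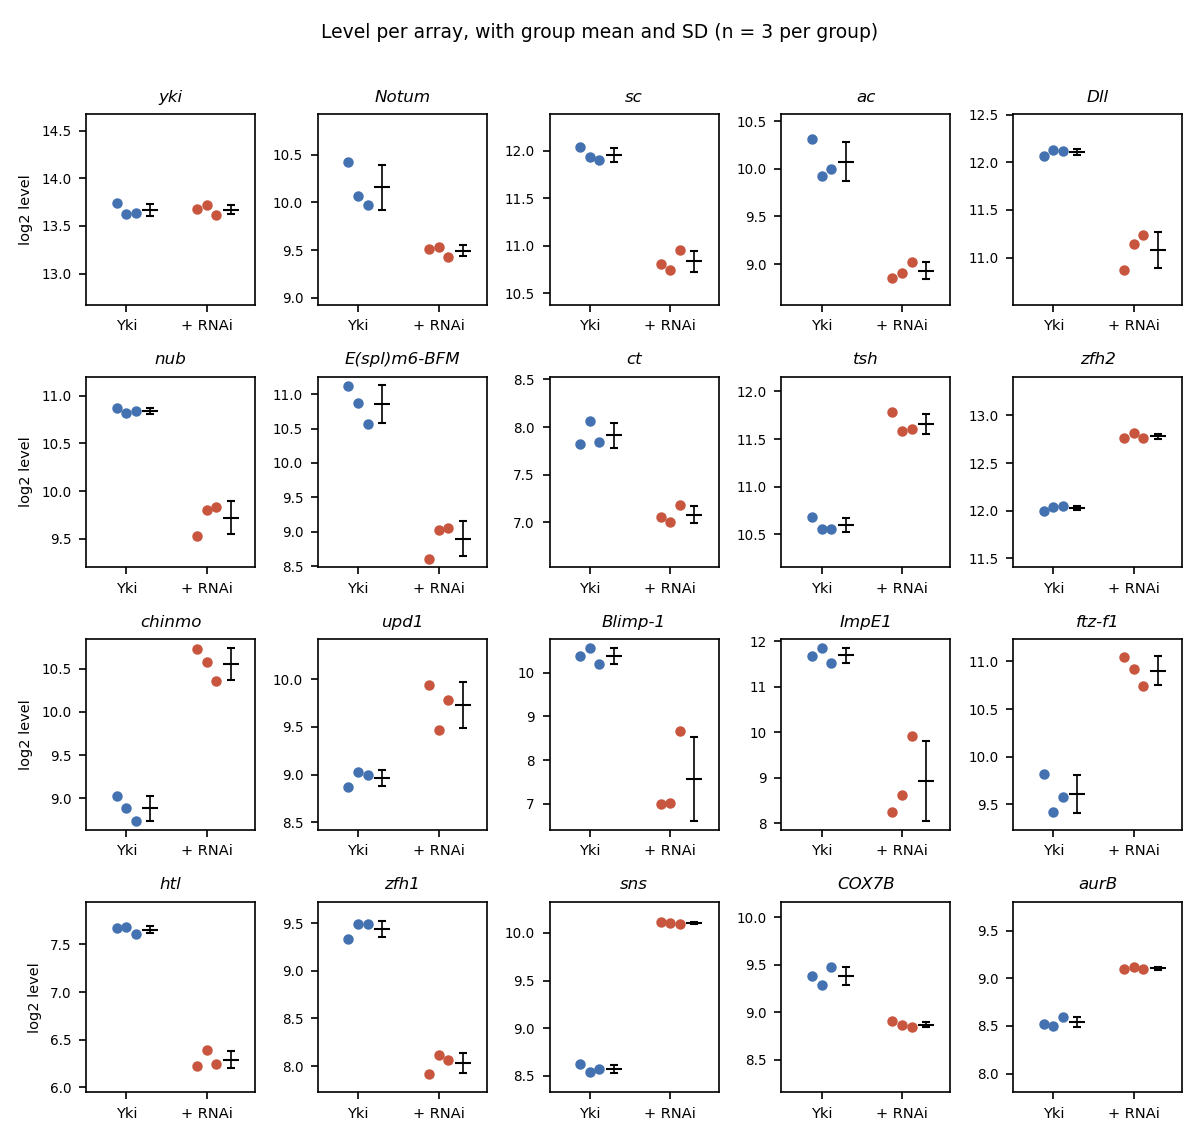
Log2 level of 20 genes in each array (points), for Yki discs (blue) and Yki + pan RNAi discs (red), with the group mean and SD in black; the vertical axes span at least 2 log2 units and do not start at 0. The arrays of the 2 groups do not overlap except for yki, whose means are both 13.67, and the 3 pan RNAi arrays differ most from each other for Blimp-1 (SD 0.96) and ImpE1 (SD 0.88).

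Most genes of the 2 cell cycle lists rose, by small amounts. For DNA replication and the G1/S transition, 14 of 23 members rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.000281, and adjusted p = 0.346 with an estimated correlation). Orc1, of the origin recognition complex, rose by 0.53 ± 0.04 (adjusted p = 0.00064), CycE by 0.38 ± 0.04 (adjusted p = 0.00192), the helicase gene Mcm6 by 0.36 ± 0.05 and dup, the fly Cdt1, by 0.34 ± 0.04. For mitosis and G2/M, 12 of 19 rose and 0 fell (12 and 0 over the list alone, 14 at an unadjusted p under 0.05 in limma), with a median of 0.25 (camera adjusted p = 0.000037, and adjusted p = 0.302 with an estimated correlation). The kinase gene aurB rose 1.48-fold (0.56 ± 0.05, adjusted p = 0.000644), and its partner Incenp and the condensin genes barr and Cap-G rose by 0.32, 0.36 and 0.27. The JAK/STAT list shifted up, with 6 of 9 members higher and 0 lower (7 and 0 over the list alone, 7 at an unadjusted p under 0.05), a median of 0.28 and a camera adjusted p of 0.000281 (adjusted p = 0.302 with an estimated correlation). Its ligand gene upd1 rose by 0.77 ± 0.12 (adjusted p = 0.00548) and the phosphatase gene Ptp61F, a STAT target and inhibitor, by 0.35 ± 0.05, beside chinmo and zfh2. Septate junction and polarity genes also shifted up, with 8 of 21 higher and 1 lower (11 and 1 over the list alone), a median of 0.15 and a camera adjusted p of 0.00237 (adjusted p = 0.302 with an estimated correlation). The neoplastic tumour suppressor genes l(2)gl (0.33 ± 0.05, adjusted p = 0.00528), dlg1 (0.27 ± 0.04) and scrib (0.25 ± 0.04) were among those that rose.

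Neither the targets of Yki nor the components of the Hippo pathway passed the camera test of a shift against other features. Tested against no change (fry), both lists passed, with an adjusted p of 0.00863 for the targets and 0.008 for the components. Of 9 measured Yki targets, 4 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.204). CycE, kibra (0.46 ± 0.05, adjusted p = 0.00219) and ex (0.24 ± 0.04, adjusted p = 0.0083) rose, while fj fell (−0.38 ± 0.05, adjusted p = 0.00244). Of 20 Hippo pathway components, 7 rose and 1 fell (9 and 2 over the list alone), with a median of 0.07 (adjusted p = 0.0895). Besides tsh, the kinase gene wts rose (0.32 ± 0.05, adjusted p = 0.00463). The lists of 4 other growth and stress pathways did not pass the camera test either. In fry, EGFR/Ras (adjusted p = 0.0309) and insulin/TOR (0.00424) passed, and JNK (0.316) and apoptosis (0.273) did not. In the EGFR/Ras list, 3 of 11 rose and 0 fell (3 and 0 over the list alone, 6 at an unadjusted p under 0.05; list adjusted p = 0.253), and these were the ligand gene spi (0.40 ± 0.06), Egfr (0.37 ± 0.04, adjusted p = 0.00218) and the repressor gene cic (0.24 ± 0.05). In the insulin/TOR list, 4 of 12 rose and 1 fell (6 and 1 over the list alone, list adjusted p = 0.123), with REPTOR at 0.56 ± 0.07, ImpL2 at 0.37 ± 0.07 and foxo at −0.28 ± 0.05 (adjusted p = 0.00848). Of 19 JNK targets, 6 rose and 4 fell (6 and 5 over the list alone, list adjusted p = 0.873), among them Atf3 (0.88 ± 0.10, adjusted p = 0.00177) and Mmp2 (−0.49 ± 0.06, adjusted p = 0.00218). Of 14 apoptosis and p53 response genes, 4 rose and 1 fell (4 and 1 over the list alone, list adjusted p = 0.609), including the DNA repair genes Irbp (0.62 ± 0.09) and Irbp18 (0.46 ± 0.08), while egr, the fly TNF, fell (−0.70 ± 0.08, adjusted p = 0.00184).

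The lists of mitochondrial energy production, protein turnover and ribosome production shifted down by small amounts. For oxidative phosphorylation, 33 of 55 members fell and 1 rose (37 and 2 adjusted over the list alone), with a median of −0.26 (camera adjusted p = 2.85e-11, and adjusted p = 0.302 with an estimated correlation). The respiratory chain and ATP synthase genes COX7B (−0.51 ± 0.06, adjusted p = 0.0020), ATPsynD (−0.46 ± 0.06) and ND-PDSW (−0.40 ± 0.05) were examples. For the proteasome, 22 of 32 fell and 0 rose (25 and 1 over the list alone, 27 at an unadjusted p under 0.05 in limma), with a median of −0.24 (camera adjusted p = 1.8e-08, and adjusted p = 0.402 with an estimated correlation). Prosalpha5 (−0.38 ± 0.05, adjusted p = 0.00375) and Prosbeta2 (−0.31 ± 0.05) encode subunits of its core. Of 39 ribosomal protein genes, 8 fell and 0 rose (8 and 0 over the list alone, 15 at an unadjusted p under 0.05 in limma), with a median of −0.08 (camera adjusted p = 0.000281, and adjusted p = 0.404 with an estimated correlation) that was −0.03 with each array centred on its median. RpL34a changed by −0.33 ± 0.05 (adjusted p = 0.00548). This list, like those of oxidative phosphorylation and the proteasome, was taken by symbol prefix. It therefore also holds genes such as RpLP0-like and RpL22-like, which both fell. RpL22-like was dim, with a mean of 5.85 with pan RNAi. In the ribosome biogenesis list, 6 of 19 fell and 1 rose (9 and 1 over the list alone), with a median of −0.16, or −0.10 after median centring (camera adjusted p = 0.000612, and adjusted p = 0.302 with an estimated correlation). Nop60B (−0.41 ± 0.05, adjusted p = 0.00257) and NHP2 (−0.36 ± 0.04), which modify ribosomal RNA, fell, while Non1 rose (0.33 ± 0.06).

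In the glycolysis list, 1 of 11 genes changed (1 over the list alone), the glucose transporter gene Glut1, which fell 2.34-fold (−1.23 ± 0.14, adjusted p = 0.00177). That list had a median of 0.01, a mean of −0.12 and no shift called (adjusted p = 0.625). Of 25 genes of glutathione metabolism, 2 rose and 1 fell (0 and 1 over the list alone, list adjusted p = 0.253). The heat shock list of 8 shifted down (median −0.93, camera adjusted p = 0.016, and adjusted p = 0.57 with an estimated correlation), but 1 member alone fell (1 over the list alone), Hsp27 (−0.45 ± 0.08, adjusted p = 0.00773). The arrays of each group differed widely in this list: its median level per array was 10.95 to 12.19 without and 10.19 to 11.54 with pan RNAi. Its shift was −0.41 without Yki + pan RNAi replicate 1. The call ended without Yki replicate 1 (adjusted p = 0.0664) and with dim features left out (adjusted p = 0.0536). Tested against no change instead of against other genes (fry), the list had an adjusted p of 0.0976.

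Genes of the ecdysone response, the steroid pulse system that times moulting and metamorphosis, made some of the largest falls, and others rose. Of 17 measured, 9 fell and 4 rose (9 and 4 adjusted over the list alone), 6 of them falling and 1 rising at least 2-fold. The list as a whole had a median of −0.19 and no shift called (adjusted p = 0.123). Beside ImpE1, ImpE2 and Blimp-1, the nuclear receptor gene Hr39 fell (−0.38 ± 0.05, adjusted p = 0.00308). The nuclear receptor gene ftz-f1, which is expressed when ecdysone titres are low, rose (1.30 ± 0.12, adjusted p = 0.000951), and so did the receptor gene EcR (0.47 ± 0.07, adjusted p = 0.00418). Blimp-1 was at 7.00, 7.02 and 8.67 in the 3 pan RNAi arrays against a mean of 10.38 without pan RNAi, and ImpE1 at 8.25, 8.61 and 9.92 against 11.68. Of 76 cuticle protein genes, 8 fell and 6 rose (8 and 5 over the list alone), and 6 fell at least 2-fold. They included Cpr12A (−1.62 ± 0.18, adjusted p = 0.00177), Cpr72Ea (−1.62 ± 0.13) and Cpr49Ah (−1.42 ± 0.15), and Cpr65Ec, whose mean of 5.41 with pan RNAi lies under the 5.91 that every feature reached in 3 arrays, so that the size of its fall is not given. The cuticle list had a median of 0.07, a mean of −0.08 and no shift called (adjusted p = 0.622). Many of its members were dim in both groups, such as Cpr47Ea (means 5.98 without and 6.01 with pan RNAi). The list test therefore says little about the cuticle genes with clear signal. Of 7 antimicrobial peptide genes, Def rose (0.77 ± 0.13, adjusted p = 0.00775; 1 over the list alone), and the list did not pass the shift test (adjusted p = 0.234).

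Markers of other cell types found in or on the disc moved as well. Of 8 markers of adult muscle precursors, the myoblasts that lie under the notum, 5 fell and 2 rose (5 and 2 adjusted over the list alone), with a median of −0.77 (camera adjusted p = 0.0243, and adjusted p = 0.346 with an estimated correlation). The transcription factor gene zfh1 (−1.41 ± 0.07, adjusted p = 0.000222), the FGF receptor gene htl (−1.37 ± 0.06, adjusted p = 0.000213) and the adhesion gene hbs (−1.03 ± 0.08) fell, whereas sns rose (1.53 ± 0.04, adjusted p = 0.0000674). The myoblast call ended with dim features left out (adjusted p = 0.217) and on ranks (adjusted p = 0.123). Of 10 tracheal markers, 4 fell and 2 rose (6 and 2 over the list alone), with a median of −0.22 (camera adjusted p = 0.0272, and adjusted p = 0.402 with an estimated correlation), including Gasp (−0.64 ± 0.06, adjusted p = 0.00125) and serp (−0.40 ± 0.04). Without pan RNAi, Gasp and serp had mean levels of 11.69 and 11.90, against 7.22 for btl, which fell too (−0.37 ± 0.06). Which cells of the dissected tissue gave these signals was not tested. The tracheal call ended without Yki replicate 1 (adjusted p = 0.0732), with dim features left out (adjusted p = 0.0536) and on ranks (adjusted p = 0.0827).

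Haemocyte markers went both ways, 5 of 12 up and 2 down (5 and 2 adjusted over the list alone, list adjusted p = 0.253). Hml (0.94 ± 0.13, adjusted p = 0.00425) and Sr-CI (0.98 ± 0.19) rose, and the collagen gene vkg fell (−0.60 ± 0.12, adjusted p = 0.0144). Of 9 markers of differentiated muscle, 2 fell and 0 rose (2 and 0 over the list alone, 3 at an unadjusted p under 0.05), TpnC73F (−0.64 ± 0.09) and Mlc2 (−0.41 ± 0.06), with a median of 0.01, a mean of −0.11 and no shift called (adjusted p = 0.234). Of 12 markers of neurons and glia, 1 rose and 1 fell (1 and 1 over the list alone, list adjusted p = 0.682). In limma, 0 of 8 fat body markers (0 over the list alone, 3 at an unadjusted p under 0.05, list adjusted p = 0.933) and 0 of 6 markers of sex composition (0 over the list alone, 1 at an unadjusted p under 0.05, list adjusted p = 0.625) passed the adjusted p. The arrays differed widely in the male-specific transcripts lncRNA:roX1 (SD 0.26 without and 0.89 with pan RNAi) and lncRNA:roX2 (SD 0.53 and 1.32), chosen after their values were seen, so a difference in sex composition was not excluded.

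**Figure D3:**
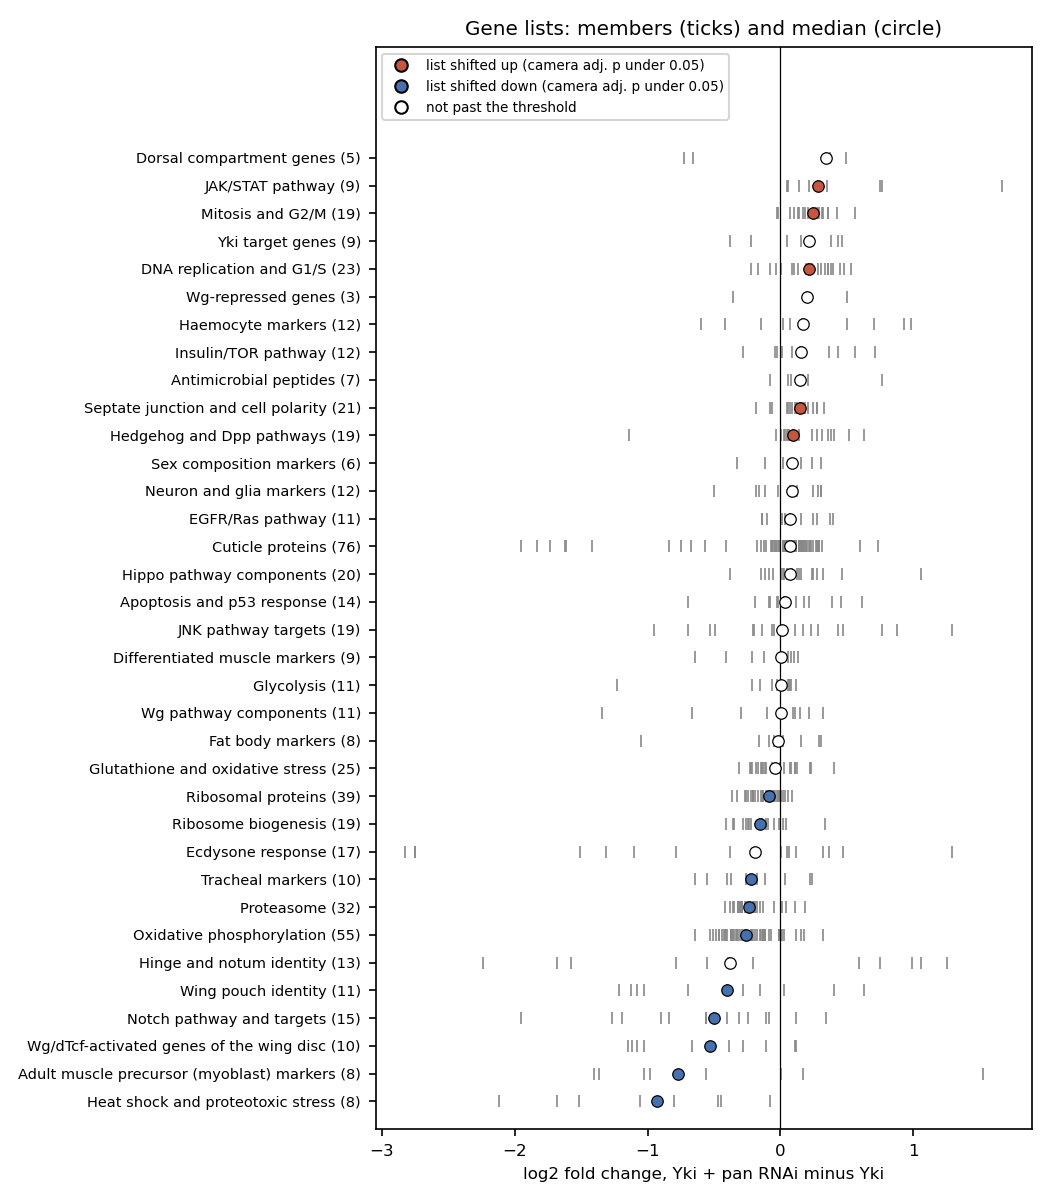
For each of the 35 tested gene lists (number of measured members in parentheses), ticks give the log2 fold change of each member, Yki + pan RNAi minus Yki, and the circle the median; filled circles mark camera adjusted p under 0.05, red for lists shifted up and blue for lists shifted down. 5 lists shifted up and 10 down, from JAK/STAT at 0.28 to heat shock at −0.93; with an estimated correlation, 0 of these calls held.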

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

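The removal of trends with gene length and with signal level was chosen after the results were seen. The 173 changed genes numbered between 147 and 196 under 16 alternatives. With the minimum lowered to a log2 fold change of 0.6 there were 476, since a lower minimum admits more genes. The 2887 features past the adjusted p alone numbered 1744 to 2435 when 1 array was left out, where fewer samples enter the fit. The 15 shifted lists numbered 12 to 16 in the other camera tests at the preset correlation or on ranks (13 to 16 on leaving out 1 array) and 0 with a correlation estimated from the arrays, where 5 lists had an unadjusted p under 0.05. In fry, which tests against no change and not against other genes, 20 lists passed, 14 of them among the 15. The remaining lists that passed were those of Yki targets, Hippo, EGFR/Ras, insulin/TOR, dorsal compartment and glycolysis genes. The labels do not say whether the numbers 1 to 3 in the titles pair the samples. Deviations of same-numbered arrays correlated at −0.127, −0.098 and 0.162. The highest correlation, 0.345, was between Yki replicate 1 and Yki + pan RNAi replicate 2. With 3 arrays per group, such correlations cannot exclude a pairing. With the replicate block, 175 genes changed, 173 of them the same genes, 2159 features passed the adjusted p, and 15 lists shifted. The change of yki, 0.00, ranged from −0.019 to 0.040 on leaving out 1 array, with a cause that was not tested. Of the planned values of single named genes, 1515 kept direction and side of the threshold, 37 lost and 7 gained the threshold and 4 changed sign, all 4 of yki. Of those of the shifted lists, 217 kept both and 23 lost the threshold, 15 of them with the estimated correlation and 1 with fry. The check of the pan knockdown was not run, and the other deposited table holds the same values, so neither gives a value here. Precision is limited by the 3 arrays per group and, for dim features, by signal close to the lowest values kept.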

Other observations

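The genes outside the naming rule that this part names were chosen after their values were seen, and so were the test of the tracheal markers and the recount over other divisions of the arrays. The members of the hinge and notum list changed in both directions. Besides tsh, zfh2 and Doc3, tio, a paralogue of tsh, rose 2.38-fold with pan RNAi, and so did Sox15 (1.29 ± 0.05), a gene of the hinge that is in none of the lists. The notum genes eyg (−2.24 ± 0.17), pnr (−1.68 ± 0.16) and tup (−1.57 ± 0.11) fell more than any pouch gene of the lists, and the Iroquois genes ara (−0.55 ± 0.05) and mirr (−0.38 ± 0.07) fell less. The partner gene of pnr, ush, rose (0.59 ± 0.07), and the Doc3 paralogues Doc1 (−0.40 ± 0.06) and Doc2 (−0.20 ± 0.05) fell, so the directions did not follow region alone, and no division by region was tested. Among single genes known from the patterning of distal appendages and leg segments, for which no list was fixed, dac rose (0.58 ± 0.06) and others fell: drm (−1.89 ± 0.10), sob (−1.84 ± 0.14) and odd (−1.40 ± 0.09), al (−1.70 ± 0.13), ss (−1.50 ± 0.12), bab2 (−1.04 ± 0.09) and the paired genes B-H1 (−1.03 ± 0.13) and B-H2 (−1.02 ± 0.10). Both genes for the ligands of the FGF receptor Htl, ths (−1.85 ± 0.11) and pyr (−1.21 ± 0.05), fell in the same discs as htl.

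Among genes tied to developmental time, the nuclear receptor genes Hr3 (−1.51 ± 0.28), Hr4 (−1.31 ± 0.20) and Eip78C (−1.10 ± 0.16) fell, and so did lncRNA:let7C (−2.28 ± 0.40), the host transcript of microRNAs that appear late in development. Genes that rose at least 2-fold included 2 of the piRNA pathway, piwi and krimp (1.37 ± 0.15). A general rise of that pathway was tested on 22 further genes, which had a median change of −0.028, with 3 higher and 4 lower (camera adjusted p = 0.954 over the 4 lists added), so the rise did not extend to the pathway as a set.

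The 3 counts of the comparison were recomputed for the 10 ways to divide the 6 arrays into 3 and 3. The real division gave 173 changed genes, 2887 features past the adjusted p and 15 shifted lists, and the highest of the other 9 gave 0, 0 and 11. The real division was the only 1 of 10 with counts as large, and 10 divisions cannot give a share under 0.1, so they are too few for a share under 0.05. Each of the other 9 sets arrays of both groups on both sides. The difference between the groups then enters the spread and part of the contrast. Their counts therefore do not show what an absent effect would give. The 11 lists came from the division that set Yki replicates 1 and 3 and Yki + pan RNAi replicate 3 against the rest.

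The downward shifts of the oxidative phosphorylation, proteasome and ribosomal protein lists, with many short and abundantly expressed genes, and the upward shifts of the replication and mitosis lists could come from a trend of the arrays with gene length or signal level. Changes did follow the genomic span weakly across 9945 genes (Spearman rho = 0.141, genes not being independent replicates), with medians of 0.02 and 0.09 in the shortest and longest decile. With each array's length trend removed, the oxidative phosphorylation median was −0.243 instead of −0.258, and with the level trend removed −0.242, and in both settings 5 of the 5 lists kept their direction and an adjusted p under 0.05. These values argue against either trend as the whole cause. A bias with transcript rather than genomic length, RNA quality and a difference in larval stage stay open. So does an effect of dTcf depletion or of changed tissue composition. None of these was tested for the 5 lists, and none of the 5 calls holds with an estimated correlation.

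The fall of ecdysone-induced genes and the rise of chinmo and ftz-f1 could reflect discs of an earlier larval stage at the same 7 days after induction. Less tracheal tissue was not excluded: the tracheal markers had a median of −0.219 (interquartile range 0.391) against −2.13 for 6 ecdysone-response genes, but these were selected by their fall, and a high baseline of many markers would hide a change in a small share of tissue. An earlier stage predicts higher Imp and lin-28, 2 early larval genes: their mean change was 0.287, Imp rose (0.43 ± 0.06, adjusted p = 0.00369) and lin-28 did not pass the threshold (0.14 ± 0.10, adjusted p = 0.359), which leaves the stage open. The broad-acting timing gene br changed by only −0.19 ± 0.06 (adjusted p = 0.046) and Eip93F, a gene of late stages, rose (0.32 ± 0.08). The pan RNAi arrays differed from each other for these genes, with ImpE2 at 9.79, 9.89 and 11.48 against a mean of 13.14 without pan RNAi, so a delay of development through dTcf depletion, a difference in staging and a local effect on these genes cannot be told apart without discs of known stage.

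The lower levels of several myoblast, notum and distal appendage genes could come from a different make-up of the dissected tissue. Notum genes were tested only in a list with hinge genes, which did not pass (camera adjusted p = 0.234). The distal appendage genes were chosen after their values were seen and were not tested as a set. Of 4 further genes enriched in myoblasts, 3 fell, with a median of −0.615 (SPARC −0.88 ± 0.07, CadN −0.90 ± 0.10, Argk1 −0.35 ± 0.05), as fewer myoblasts per disc would predict, while Ama (0.07 ± 0.06) did not pass the threshold and sns, kirre (0.01 ± 0.07) and rols (0.17 ± 0.05) of the fixed list did not fall. Of 5 genes of ventral discs, which leg disc tissue carried along in the Yki samples would raise there, 3 fell. Sp1 changed by −0.82 ± 0.18, disco by −0.59 ± 0.07 and disco-r by −0.77 ± 0.14. The gene btd (−0.43 ± 0.15) did not pass the threshold and dac rose (0.58 ± 0.06). The median of the 5, −0.590, is the value of disco. The mean of disco with pan RNAi, 5.82, lies under the 5.91 that every feature reached in 3 arrays, so this median is uncertain. With camera over the 4 lists added, the myoblast genes had an adjusted p of 0.0176 and the ventral disc genes one of 0.105, both at the preset correlation alone and with no test of their difference, so both explanations stay open. Lower expression of these genes within an unchanged tissue is another explanation. It was not tested. Nor was a part of tissue make-up or larval stage in the falls of the Wg-activated genes ac, sc and Dll and the Notch targets. The same holds for the rises in the JAK/STAT list, where chinmo is also a gene of early larval states and zfh2 a hinge gene.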
